A study of Mus musculus with 6 samples.

How the data were processed

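Total RNA from 6 samples of mouse oligodendrocyte precursor cells, 3 infected with a control retrovirus and 3 with a Chd7 knockdown retrovirus, was isolated with an RNeasy kit, amplified as amino allyl RNA and coupled to Cy5 after the array maker's (TORAY) procedure, per the labels' protocols. Each array was read at 635 nm at 3 gains joined by least squares, per the file headers, and the deposited intensity is the median of each spot. The scanner software is not given in the sources used here. Each array held 27456 spots, of which 3982 were controls or empty, and 23473 probes. The deposited local background intensity followed the spot's own signal (correlation of logs 0.959 to 0.983), so it was not used as a background. A second set of intensity values deposited by the authors was compared with the scanner values: each column was the spot signal less about the mean of the blank spots, times a factor that set the median to 25, rounded (99.995% of residuals within 0.6). This was recovered from the values, and no source states it. These values have no log, no gene centring and no direction of their own.

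Spot intensities were corrected with normexp without local background (offset 50, fitted on all spots), quantile normalized between arrays and averaged per probe on the log2 scale in limma 3.58.1 (statmod 1.5.0, R 4.3.3). Figures were drawn with matplotlib 3.10.9. The offset shrinks the changes of dim genes, and the authors' values give larger ones. A probe was tested if its raw signal exceeded the mean of the blank spots by 2 SD on at least 3 of the 6 arrays, and 1 gene probe marked as bad at every gain on an array was left out. Over all arrays 13 spots were so marked at any gain. Gene symbols came from the platform annotation: 20690 probes had 1 symbol, 2783 had none and 0 had several. Of these, 20556 matched a RefSeq table (GRCm38.p6) by Entrez ID, and 0 symbols changed. A gene with several probes was represented by the probe with the highest mean. Of 140 other probes of 133 genes that passed, 107 had the same sign and 32 passed in the same direction, with 0 passing in the opposite direction.

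Groups were compared with limma (lmFit and eBayes with a trend) and Benjamini-Hochberg adjustment over 17422 genes. The p-values of limma are two-sided. The 24 gene lists were fixed before the data were examined, and 23 had the 5 tested members needed for camera with a preset correlation of 0.01. Camera was repeated with an estimated correlation. The fry test, which compares a list with no change and not with the other genes, was also run. Named genes were Chd7 and its family, of each list at least the up to 4 members with the smallest p, and the 12 highest positive and 12 largest negative changes among genes that passed and whose groups did not overlap. Further list members were named as examples after their values were seen. Chic2, Gsx2, H1f2, H4c12, H4c2, H4c14, Gbp4, Cox5a and Cox7a1 belong to no list and were chosen after their values were seen.

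The labels give both groups the numbers 1 to 3 without saying what a number marks. Deviations from the group means correlated at 0.36, 0.38 and 0.23 between samples of the same number, and each array correlated best with its own number. The numbers may thus pair the samples, which is inferred from the data. With 3 arrays per group such a match can also arise by chance. Counts and p-values come from the fit without the number as a block, unless stated. The fit with the number as a block is given where it changes a call. Slopes between gains in the file headers formed 2 sets, of control replicates 1 and 2 with knockdown replicate 2 (0.464 to 0.467) and of control replicate 3 with knockdown replicates 1 and 3 (0.478 to 0.479), which were treated as possible batches.

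Alternatives were no background correction, an offset of 16, median scaling, cyclic loess, the authors' values, other filters on dim probes, other variance models, array weights, the replicate block, an adjusted threshold of 0.1, each probe by itself and leaving out each array. The procedure was tested on simulated data for this comparison with 200 of 17422 genes changed, all with a mean log2 intensity above 7. Of these, 76% of the 1.5-fold and 92% of the 2-fold changes were recovered with 7 false calls. With the block 56% and 89% were recovered with 4 false calls. Of 200 unchanged lists 5 reached p below 0.05 in camera. The simulated noise was independent between genes and held no replicate effect. Changes of dim genes, lists of correlated genes and paired arrays were thus not covered.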

Results

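RNA was profiled from oligodendrocyte precursor cells, the glial progenitors that give rise to myelin-forming oligodendrocytes, taken from forebrains of mouse embryos of the Jcl:ICR stock at stage E15.5. The cells were grown with the mitogens FGF2 and PDGF-AA, infected with a control retrovirus or a retrovirus that knocked down Chd7, and harvested 3 days after infection. Each group held 3 samples, and each sample was hybridised to its own one-colour array. The median raw signal per array was 83.4 to 89.4, against a mean of 58.9 to 61.9 on blank spots, and 87.0% to 89.8% of probes lay above the detection limit. The number of arrays limits the precision of each value. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

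Chd7, which encodes an ATP-dependent chromatin remodeller of the CHD family, was lower on each knockdown array than on each control array. Its log2 intensity was 9.44, 9.20 and 9.47 in control replicates 1 to 3 and 8.54, 8.44 and 8.48 in knockdown replicates 1 to 3. The group means were 9.37 ± 0.15 (SD, n = 3) and 8.49 ± 0.054 (SD, n = 3), a log2 fold change of -0.88 (SE 0.0855, adjusted p = 0.00112), which left 54.3% of the control signal. In the authors' own processed values 48.9% remained. The other Chd7 probe read 7.81, 7.60 and 7.62 in the controls and 7.20, 7.23 and 7.15 in the knockdown, a log2 fold change of -0.48 (SE 0.0676, adjusted p = 0.00411 over all probes). Within each group of arrays that shared a scanner gain, 2 arrays of one condition stood against 1 of the other, and the Chd7 log2 fold change was -0.88 (adjusted p = 0.104) and -0.95 (adjusted p = 0.0595). In these fits the lone array was assumed to vary like the others.

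Of the 10 CHD genes tested, Chd7 fell and Chd3, a subunit of the NuRD complex, rose by 0.30 on the log2 scale. The Chd3 call was lost without control replicates 2 or 3 or knockdown replicates 1 or 3 (adjusted p up to 0.0823), and the other Chd3 probe read 0.16. Chd3 also did not pass with median scaling (0.0829) or in the authors' values (0.0566). The same held with gain group as a block (0.0625) and without both arrays numbered 1 (0.0854). The other 8 members did not pass, with log2 fold changes of 0.21 for Chd1, -0.10 for Chd2, -0.27 for Chd4, -0.0046 for Chd5, 0.02 for Chd6, -0.07 for Chd8, 0.04 for Chd9 and 0.03 for Chd1l. When adjusted over the list alone, 1 member rose and 2 fell. The list's median was 0.0075, its mean was -0.07 and the test pointed down, so the signs differed (adjusted p = 0.779, and 0.858 with an estimated correlation). With the replicate number as a block Chd4 passed as well (adjusted p = 0.0405), and without control replicate 3 Chd1 did (0.016).

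The arrays separated by group. The first principal component held 54.7% of the variance and parted the 3 knockdown from the 3 control arrays, and the second held 20.3% and set the arrays numbered 1 of both groups apart from the rest. The Pearson correlation across all 20997 tested probes averaged 0.9970 between arrays of the same group (0.9956 to 0.9978) and 0.9936 between groups (0.9922 to 0.9955). Probes are not independent replicates, so these correlations carry no test.

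**Figure D1:**
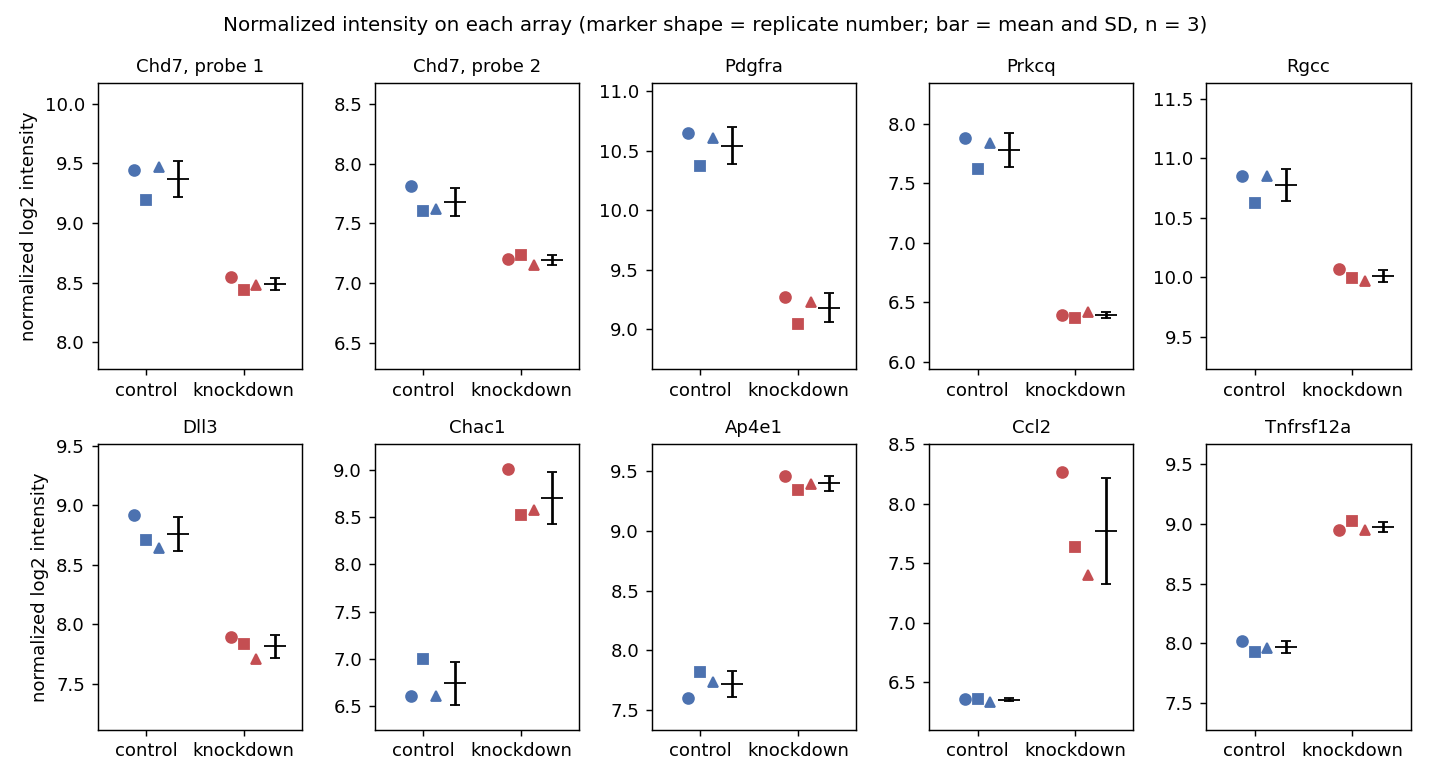
Normalized log2 intensity of selected genes on each of the 6 arrays, with 1 point per array (shape shows the replicate number) and bars for the group mean and SD (n = 3); each panel has its own vertical range. Chd7 lay at 9.20 to 9.47 on the control arrays and at 8.44 to 8.54 on the knockdown arrays.

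Among 17422 genes tested, 1677 differed between knockdown and control at an adjusted p below 0.05 in limma, 781 higher and 896 lower. The arrays of both groups did not overlap for 5201 tested genes (29.85%, against 10% by chance). At a change of at least 1.5-fold and an unadjusted p below 0.01 there were 178 genes, 90 higher and 88 lower. At least 2-fold changes past the adjusted threshold numbered 23, of which 9 were higher and 14 lower. With the replicate number as a block 2581 genes passed, 1286 higher and 1295 lower. In the authors' processed values 960 passed, 286 higher (29.8%, against 46.6%) and 674 lower. Within the groups of arrays sharing a scanner gain, each with 2 arrays against 1, 39 genes passed (24 higher, 15 lower) and 39 genes passed (10 higher, 29 lower).

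The count depended on which arrays were used. It was 1453 without control replicate 1, 951 without control replicate 2, 1061 without control replicate 3, 748 without knockdown replicate 1, 858 without knockdown replicate 2 and 990 without knockdown replicate 3, and 623 of the 1677 genes (37.1%) passed in each of the 6 fits that left out 1 array.

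The genes with the highest positive changes were led by Chac1, a glutathione-degrading enzyme induced in the integrated stress response (log2 fold change 1.96, SE 0.145, adjusted p = 4.2e-04). Ap4e1, a subunit of the AP-4 vesicle adaptor, rose by 1.68 on 1 probe and read 0.06 on the other. The chemokine genes Ccl2 and Cxcl1 rose by 1.41 and 1.07, the glycine transporter gene Slc6a9 by 1.16, and Igfbp3, which binds insulin-like growth factors, by 1.07. Olfml3, a secreted matrix protein gene, rose by 1.08 on 1 probe and read -0.0046 on the other. Apoc1, an apolipoprotein gene, rose by 1.01, and Tnfrsf12a, the receptor for the cytokine TWEAK, by 1.01. The histone genes Hist2h2bb, H4c18 and H4c8 rose by 0.99, 0.98 and 0.96. Their copies are near-identical in sequence, so the signal of each cannot be assigned to that copy with certainty. In the authors' processed values Slc6a9 (adjusted p = 0.0559) and Hist2h2bb (0.0517) did not pass and Olfml3 stood at 0.050. Without both arrays numbered 1 Apoc1 did not pass (0.0518).

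The genes with the largest negative changes included Dpysl3, a regulator of the growth cone cytoskeleton (log2 fold change -1.47, SE 0.169, adjusted p = 0.0019), and Pdgfra, the receptor for the PDGF-AA in the medium (-1.36, SE 0.098, adjusted p = 4.2e-04). Prkcq, which encodes a protein kinase C isoform, fell by 1.38 on 1 probe, while a dimmer probe read 0.01. Sh3gl3, an endophilin gene, fell by 1.22, Vxn by 1.12, Ppp2r2b, a regulatory subunit of protein phosphatase 2A, by 1.11, and Rlbp1, a retinaldehyde-binding protein gene, by 1.11. Actc1, a sarcomeric actin gene, decreased by 1.06, the small GTPase gene Rab33a by 1.04 and Ugdh, which makes the UDP-glucuronate used for glycosaminoglycans, by 1.04. Lnx1, a ubiquitin ligase gene, dropped by 1.02, and Rufy3, which acts in axon growth, fell to a knockdown-over-control ratio of 0.499.

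Rgcc and Prkcq, the tested genes known from the study's own follow-up, both fell (Rgcc by 0.76 on the log2 scale), over all genes and adjusted over the list alone. This list was chosen on these samples and is not independent evidence of its direction. It held too few tested genes for a list test, and its other member was not analysed here.

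Of 22 precursor markers tested, 7 fell, none rose and 15 did not pass. Beside Pdgfra and Rlbp1, these were Cspg4, which encodes the NG2 proteoglycan (-0.48), Lhfpl3 (-0.96), the AMPA receptor auxiliary protein gene Cacng4 (-0.52), and the lineage transcription factor genes Sox10 (-0.52) and Olig2 (-0.35). Olig2 did not pass without knockdown replicates 2 or 3 (adjusted p up to 0.0666). It also did not pass with median scaling (0.133), in the authors' values (0.0545) or without both arrays numbered 1 (0.0513). With p adjusted over the list alone 1 rose and 9 fell. The list fell as a set (median -0.14, adjusted p = 1.54e-05), a call lost at adjusted p = 0.317 with an estimated correlation. With the replicate block 1 rose and 10 fell, Ednrb among those that passed (log2 fold change 0.31, adjusted p = 0.0261) with Olig1 (-0.24, adjusted p = 0.037).

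Of 17 tested genes linked to Chd7 in other work, 4 fell and none rose: Sox9 (-0.50), Sox4 (-0.64), Sox10 and Olig2, all transcription factor genes. It shares 5 members with the precursor list, among them Olig2 with the limits given above. Adjusted over the list alone 5 fell. The list passed (median -0.04, adjusted p = 0.032, and 0.355 with an estimated correlation), but not without control replicate 1 (0.0648) or knockdown replicate 1 (0.0913), in the authors' processed values (0.0716), without the variance trend (0.0519) or with gain group as a block (0.0699). Counted with the replicate block 6 fell.

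Of 21 neural progenitor genes 3 fell and none rose. These were Hes5, a Notch effector (-0.78), Sox4, and Ezh2, the methyltransferase of Polycomb complex PRC2 (-0.34). Ezh2 was lost without knockdown replicates 1 or 2 (adjusted p up to 0.0632). Lhx2 read -0.31 and passed with the replicate block (adjusted p = 0.0417) and without control replicate 2 (0.0403). When adjusted over the list alone 5 fell, as with the block. The list passed (median -0.04, adjusted p = 0.0339, and 0.44 with an estimated correlation) but was lost without control replicate 1 (0.116), knockdown replicate 1 (0.055) or knockdown replicate 2 (0.0545), without the variance trend (0.0519) and in fry (0.0503).

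Of 24 genes of differentiating oligodendrocytes and myelin, 1 rose, 4 fell and 19 did not pass. The receptor gene Gpr37 rose by 0.46, while Bcas1 (-0.67), Gal3st1 (-0.52) and Ugt8a (-0.54), the last 2 of which make the myelin lipid sulfatide, fell along with the transcription factor gene Zfp488 (-0.09). Ugt8a was lost without control replicates 2 or 3 or knockdown replicate 1 (adjusted p up to 0.0606). Zfp488, near the floor, did not pass in the authors' values (0.0758) or without both arrays numbered 1 (0.0595). Mbp, the myelin basic protein gene, read 0.17 (SE 0.293). The same 1 and 4 genes passed in number when adjusted over the list alone, and 4 rose and 4 fell with the replicate block. Without control replicate 2 or knockdown replicate 2, 2 rose, and in the authors' values 0 rose and 3 fell. The list's median was 0.01, its mean -0.03 and the test pointed down without passing (adjusted p = 0.605, and 0.915 with an estimated correlation).

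Of 25 G2/M genes tested, 9 fell, none rose and 16 did not pass, and all 25 had negative values. The number that fell was 2 with median scaling, 4 without knockdown replicate 2, and 5 without control replicate 2, knockdown replicate 1 or knockdown replicate 3. The spindle factor gene Tpx2 (-0.43), the topoisomerase gene Top2a (-0.37), the ubiquitin-conjugating enzyme gene Ube2c (-0.38) and the checkpoint kinase gene Ttk (-0.34) had the smallest p. Of these, Top2a and Ube2c did not pass with median scaling (adjusted p = 0.069 and 0.0814). Ccna2 (-0.34), Cdc20 (-0.33), Cdk1 (-0.28) and the proliferation marker gene Mki67 (-0.28) fell as well. These were less firm: Cdk1 and Mki67 did not pass without any 1 of the 6 arrays (adjusted p up to 0.103 and 0.124), Ccna2 not without control or knockdown replicate 2 (up to 0.0646), Cdc20 not without control replicate 3 or knockdown replicates 1 or 3 (up to 0.0672), and Ttk not without knockdown replicate 2 (0.0539). With p adjusted over the list alone 16 fell. The list test gave a median of -0.25 and adjusted p = 1.10e-08, lost at adjusted p = 0.317 with an estimated correlation.

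Of 28 G1/S genes 2 rose and 4 fell. The D cyclin genes Ccnd2 (0.43) and Ccnd3 (0.31) rose, while their kinase gene Cdk4 (-0.47) and the replication genes Fen1 (-0.34) and Mcm7 (-0.38) fell. Ccnd3 was lost without knockdown replicates 2 or 3 (adjusted p up to 0.0739), Fen1 without knockdown replicates 1 or 2 (up to 0.0597) and Mcm7 without knockdown replicate 2 (0.0658). Adjusted over the list alone 2 rose and 5 fell, and the list did not pass (adjusted p = 0.196, and 0.781 with an estimated correlation), except in the authors' values (0.0473) and without knockdown replicate 3 (0.0359). With median scaling, and without knockdown replicate 2, 1 rose and 1 fell. Without knockdown replicate 1, 2 fell, and without knockdown replicate 3, 1 rose. Of 14 CDK inhibitor and cell-cycle exit genes 1 rose and 3 fell. Cdkn1a (p21) rose by 0.61, and Cdkn1c (p57, -0.93), Rgcc and Cdkn2d (p19, -0.36) fell. Rgcc is also a follow-up gene chosen on these samples, so its fall is not independent evidence for this list. When adjusted over the list alone 2 rose and 4 fell. The list did not pass (adjusted p = 0.058, and 0.355 with an estimated correlation) with all arrays and the preset settings, but lay close to the threshold. It passed with the replicate block (0.0468, with 2 that rose and 3 that fell), median scaling (0.0404) and cyclic loess (0.0485). It passed too in the authors' values (0.0391), with no filter on dim probes (0.0458) and with array weights (0.0385). It also passed without control replicate 3 (0.0158), knockdown replicate 2 (0.041) or knockdown replicate 3 (0.048). In fry, a test against no change, the list passed as well (0.0202). In the authors' values, and without both arrays numbered 1, Cdkn1a did not pass (0.0525 and 0.0519).

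Of 22 p53 target genes 7 rose and none fell. The number was 3 with median scaling or without knockdown replicate 2, and 4 in the authors' values, without control replicate 3 or without knockdown replicate 3. They included Phlda3, an inhibitor of Akt (0.64), Zmat3 (0.45), Cdkn1a, Ccng1 (0.37) and Mdm2, the ubiquitin ligase that degrades p53 (0.30). Ccng1 was lost without knockdown replicate 2 (adjusted p = 0.0517) and Mdm2 without any 1 of the 6 arrays (up to 0.131). With p adjusted over the list alone 9 rose. The list rose as a set (median 0.14, adjusted p = 7.88e-04), lost at adjusted p = 0.317 with an estimated correlation.

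Of 20 integrated stress and unfolded protein response genes 7 rose and 2 fell. Those that rose included Chac1, Atf4 (0.74), Atf5 (0.65), Ddit3, which encodes CHOP (0.64), the asparagine synthetase gene Asns (0.68) and Vldlr (0.69), which are targets or members of the Atf4 arm. Xbp1 (-0.43) and Sdf2l1 (-0.37), of the endoplasmic reticulum arm, fell, and the chaperone gene Hspa5 read -0.03. In the authors' values 4 rose. Xbp1 was lost without control replicates 1 or 2 or knockdown replicates 1 or 2 (adjusted p up to 0.103) and Sdf2l1 without knockdown replicates 1 or 2 (up to 0.0579). Adjusted over the list alone 9 rose and 3 fell. The list rose as a set (median 0.07, adjusted p = 0.00158), lost at adjusted p = 0.317 with an estimated correlation.

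Of 31 interferon response genes 8 rose and none fell, with small changes near the dim end of the scale. Igtp, an interferon-inducible GTPase gene, rose by 0.67 (0.50 on the other probe), Gbp3 by 0.39, Usp18 by 0.37, Irf9 by 0.35, Cxcl10 by 0.33, Ifi35 by 0.29, Xaf1 by 0.20 and Ifit1 by 0.09. Isg15 read 0.09 (SE 0.0553). Ifit1, near the floor, did not pass with median scaling (adjusted p = 0.141), without the variance trend (0.0601) or without both arrays numbered 1 (0.0804). The number that rose was 5 without knockdown replicate 1 or 2 and in the authors' values. Gbp3 was lost without control replicate 3 or knockdown replicates 1 or 2 (adjusted p up to 0.0591), Irf9 without control replicate 2 or knockdown replicates 1 or 2 (up to 0.0683), and Cxcl10 without control replicates 2 or 3 or knockdown replicates 1 or 2 (up to 0.111). When adjusted over the list alone 13 rose. The list rose as a set (median 0.08, adjusted p = 1.54e-05), lost at adjusted p = 0.317 with an estimated correlation. The list's median was 0.14 with an offset of 16 and 0.29 in the authors' values, so its size depended on the processing.

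Of 18 cholesterol synthesis genes 1 rose and 3 fell, over all genes and adjusted over the list alone. Hmgcs1 (-0.48, and -0.56 on the other probe), Mvd (-0.43) and the regulator gene Srebf2 (-0.24) fell, while Hsd17b7 rose by 0.44. Hmgcs1 and Mvd passed only without control replicate 3 among the 6 fits that left out 1 array (adjusted p up to 0.129 and 0.116), and Srebf2 only without knockdown replicate 1 (up to 0.101). The list fell as a set (median -0.18, adjusted p = 0.0397, and 0.477 with an estimated correlation), but not without control replicates 1 (0.0703) or 2 (0.16) or knockdown replicates 1 (0.131) or 3 (0.052), without the variance trend (0.0594), with gain group as a block (0.113) or in fry (0.258). In the authors' values 1 rose and 0 fell. With the replicate block 1 rose and 5 fell.

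Of 14 Notch pathway genes 3 fell: the ligand gene Dll3 (-0.94), Hes5, and the feedback inhibitor gene Nrarp (-0.78). The ligand gene Jag1 read 0.09 and passed without control replicate 2 (adjusted p = 0.0403). With p adjusted over the list alone 1 rose and 5 fell, and the list did not pass (adjusted p = 0.0697, and 0.317 with an estimated correlation) but lay close to the threshold. It passed with the replicate block (0.0456), median scaling (0.0445) and array weights (0.0385). It also passed without control replicate 1 (0.0391), knockdown replicate 2 (0.0458) or knockdown replicate 3 (0.048). In fry, a test against no change, the list passed as well (0.01). Of 22 genes that respond to FGF and PDGF through ERK, 2 rose and 2 fell. The feedback phosphatase gene Dusp6 rose by 0.77 and Ier3 by 0.91, while Phlda1 (-0.34) and the ERK inhibitor gene Spred1 (-0.23, -0.09 on the other probe) fell. Spred1 passed only without control replicate 3 among the fits that left out 1 array (adjusted p up to 0.136). Adjusted over the list alone 2 rose and 4 fell, and the list did not pass (adjusted p = 0.779, and 0.858 with an estimated correlation).

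Of 15 BMP and TGF-beta response genes the matrix protein gene Ccn2 rose by 0.61, and Id2 (-0.74) and Id3 (-0.48), inhibitors of bHLH factors, fell. Id3 was lost without control replicate 2 or knockdown replicates 1 or 3 (adjusted p up to 0.0554). Bmp4 (-0.24) passed with median scaling (adjusted p = 0.0406), without control replicate 2 (0.0017) and with the replicate block (0.0126). With the block 1 rose and 4 fell, the same numbers as adjusted over the list alone. The list did not pass (adjusted p = 0.216, and 0.477 with an estimated correlation). None of 13 Wnt response genes passed on either adjustment by the probe that stood for the gene (Dkk3 0.18, Bambi 0.14, Wif1 -0.05 and Lgr5 0.03; list adjusted p = 0.561, and 0.781 with an estimated correlation). The other Lgr5 probe, near the floor, did pass in the opposite direction (-0.09, adjusted p = 0.024 over all probes). Of 15 hypoxia and glycolysis genes the peptide hormone gene Adm rose by 0.70 and Ankrd37 (-0.16) fell, the latter not without control replicate 2 or knockdown replicates 1, 2 or 3 (adjusted p up to 0.111). Pgam1 read 0.23, and Pfkl (-0.21) passed with the block (0.0313), where 1 rose and 4 fell. Without control replicate 3, 2 fell. When adjusted over the list alone 1 rose and 1 fell. The median was 0.03, the mean -0.02 and the test pointed down without passing (adjusted p = 0.773, and 0.929 with an estimated correlation). Of 18 ribosome biogenesis genes Rrs1 rose by 0.32 on both adjustments, not without control replicate 2 or knockdown replicates 1, 2 or 3 (adjusted p up to 0.0933). Polr1a read 0.08, Polr1b 0.15 and Ncl -0.22, the list did not pass (adjusted p = 0.394, and 0.817 with an estimated correlation), and 2 rose with the block. Polr1b passed without control replicate 1 (0.0349) and with array weights (0.0499).

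Markers of other cell types differed in direction. Of 21 astrocyte markers Acsbg1 rose by 0.50 and Sox9 and Id3 fell, while Gfap, the astrocyte filament gene, read 0.05 near the floor. With p adjusted over the list alone 2 rose and 2 fell, and 3 and 3 with the replicate block, Gjb6 (0.19) among them (adjusted p = 0.0179). Gjb6 also passed with median scaling (0.0336) and without knockdown replicate 1 (0.0489) or 2 (0.043), and 2 markers rose without control replicate 1. The list did not pass (adjusted p = 0.961, and 0.98 with an estimated correlation). Of 24 neuron markers 2 rose and 5 fell, also when adjusted over the list alone. The migration gene Dcx (-0.71), the RNA-binding protein gene Elavl4 (-0.60, -0.46 on the other probe) and the growth cone gene Gap43 (-0.84) fell, and the interneuron transcription factor genes Dlx1 (0.38) and Dlx2 (0.25) rose. Gap43 was lost without control replicates 2 or 3 or knockdown replicate 1 (adjusted p up to 0.0941) and Dlx1 without knockdown replicates 2 or 3 (up to 0.0685). The number that fell was 2 without control replicates 2 or 3 or knockdown replicate 1, and 3 without control replicate 1 or knockdown replicate 2, with median scaling and in the authors' values. The list did not pass (adjusted p = 0.216, and 0.781 with an estimated correlation). None of 15 microglia markers passed on either adjustment (Laptm5 0.07, P2ry12 0.07, C1qc 0.06 and C1qa -0.02; list adjusted p = 0.365, and 0.781 with an estimated correlation). None of 14 vascular and mesenchymal markers passed either (Dcn 0.04, Col6a1 0.05, Lum -0.04 and Tagln 0.23; list adjusted p = 0.588, and 0.812 with an estimated correlation), and Tagln passed with the block (0.00616).

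Of 12 reference genes Gusb rose by 0.37 and Hprt fell by 0.34. Gusb passed only without knockdown replicate 3 among the fits that left out 1 array (adjusted p up to 0.129), and Hprt was lost without control replicates 2 or 3 or knockdown replicates 1 or 3 (up to 0.101). Actb read -0.06, Gapdh 0.0060, Sdha 0.19 and Tfrc 0.30, of which Tfrc passed with the replicate block (adjusted p = 0.0343). Adjusted over the list alone 2 rose and 1 fell. The median was -0.03, the mean 0.01 and the test pointed down without passing (adjusted p = 0.928, and 0.929 with an estimated correlation).

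**Figure D2:**
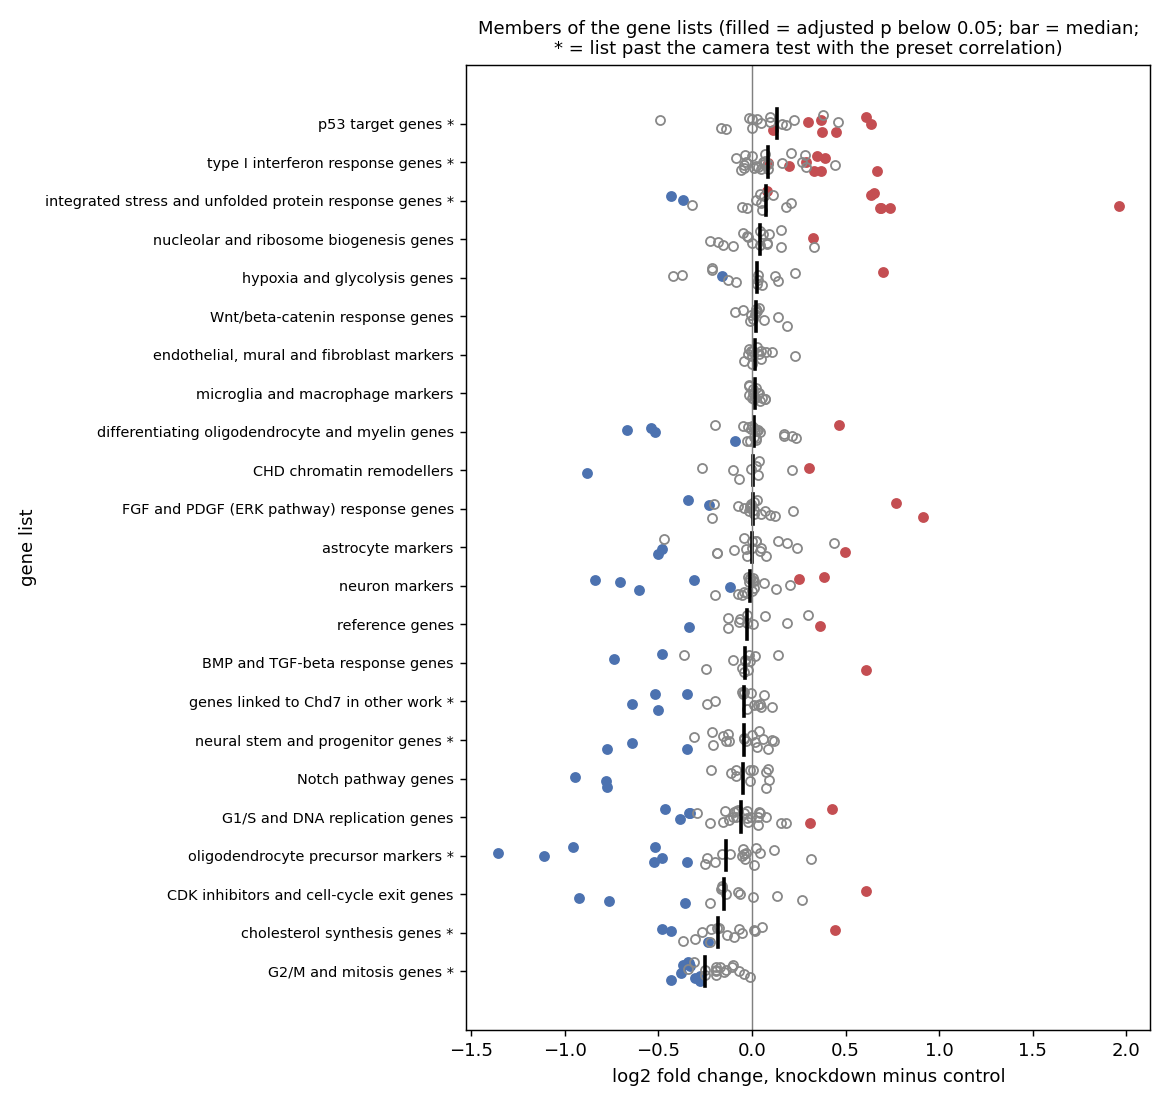
Log2 fold changes, knockdown over control, of the tested members of each gene list, with 1 point per gene (filled where adjusted p was below 0.05), a bar at each list's median and an asterisk on lists that passed with the preset correlation, none of which passed with an estimated one. All 25 G2/M genes lay below 0, and 24 of the 31 interferon response genes lay above 0.

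In all, 8 of the 23 tested lists passed, 3 up and 5 down, and none passed with an estimated correlation. The adjusted p of 0.317 in camera with an estimated correlation was shared by several lists, so it does not rank them. Before adjustment their p ran from 0.0281 for the G2/M list to 0.0827 for the Notch list. Spots without a probe rose above the detection limit less often on knockdown arrays (79, 56 and 69 of 1102) than on control arrays (156, 150 and 291), which bears on dim genes such as those of the interferon, microglia and vascular lists.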

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

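Probes without a gene symbol took no part in the gene comparison. Of 2370 such probes tested, 75 were higher and 82 lower in the knockdown at an adjusted p below 0.05 over all probes in limma, a share of 6.62% against 9.11% of the probes with a symbol. They stand here because they carry a difference between the groups that the gene comparison did not use. The probe with the highest positive change, M400011249, read 0.84 (SE 0.0903, adjusted p = 0.00156), and the probe with the largest negative change, M400011927, read -0.82 (SE 0.106, adjusted p = 0.00301).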

How the results depend on the processing

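Leaving out both arrays numbered 1 and treating gain groups as batches were chosen after seeing the data. The cause of the shifts given here was not tested, unless fewer arrays or the threshold itself is the difference. The count of 1677 genes was 960 in the authors' processed values (911 shared), 2581 with the replicate block (1674 shared), 800 without both arrays numbered 1, 39 and 39 within the gain groups, 1160 with gain group as a block, and 2687 at an adjusted p below 0.1. The count of 178 genes changed 1.5-fold was 302 with an offset of 16 and 625 in the authors' values. Within the gain groups 1 condition had a lone array, assumed to vary like the others, and Chd7 read -0.88 and -0.95 and did not pass. So small a design says nothing about the stability of Chd7 or of the count. The 8 lists became 5 without the variance trend, 5 without both arrays numbered 1 and 0 with an estimated correlation. Leaving out 1 array gave 748 to 1453 genes, 145 to 210 genes changed 1.5-fold, a Chd7 log2 fold change of -0.97 to -0.83, 5 to 10 lists, and a gap between within-group and between-group correlation, taken over the 17422 genes and not over all probes, of 0.00308 to 0.00420 (0.00374 with all arrays). Of the 1677 genes 623 (37.1%) passed without each of the 6 arrays. The genes named in the text were firmer, because the rule takes small p and large changes: 76 of 109 that passed, the other Chd7 probe included, did so without each array, and 33 did not. Of the named genes that passed, 29 did not in the authors' values, 32 without both arrays numbered 1, 21 with median scaling, 15 with gain group as a block, 8 without the variance trend, 4 with robust variances, 1 with cyclic loess and 1 with array weights. No named gene or list that passed changed sign under these alternatives; for genes this was fixed in advance wherever arrays were only left out, since the groups did not overlap for any of the 1677. With the replicate block 12 G2/M genes and 4 Notch genes fell, 9 p53 target and 12 interferon genes rose, 8 stress response genes rose and 3 fell, 3 ERK response genes rose and 3 fell, and 3 neuron markers rose and 6 fell. Among the named genes and the list tests, the block changed no other call than those given with the results. Signal over background limits the dim genes: 10477 of the tested genes, 600 of them among the 1677, had a mean log2 intensity below 7, where the offset shrinks differences.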

Other observations

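The tests of the other Ap4e1 probe, of the precursor markers, of families of genes with a shared name, and of neighbours without histone genes or shared name roots were chosen only after the result was seen. Leaving out both arrays numbered 1 was chosen after seeing the data, before the interferon list was tested that way, and the other tests were set out first. Of 11 histone H4 genes 10 rose (median 0.65), among them H4c12 (0.85) and H4c2 (0.74), while H4c14 read 0.0065. In each scaling 10 passed, and 8 in the authors' values. Other histone families did not pass, though H2B and H3 leaned upward. Of 16 H2B genes 3 rose and none fell, and 14 had positive values (median 0.13, adjusted p = 0.0679 in camera). Of 9 H3 genes 2 rose and none fell, and 7 had positive values (median 0.16, adjusted p = 0.219). In the authors' values 0 H2B genes and 1 H3 gene rose. Of 9 linker histone H1 genes 2 rose, among them H1f2 (0.69, and adjusted p = 0.0538 in the authors' values). The family median was 0.0061 (adjusted p = 0.832), and -0.0081 with median scaling. Of 14 H2A genes 2 rose and 2 fell, and 11 had negative values (median -0.16, adjusted p = 0.256). Over 312 families the H4 family led (adjusted p = 7.43e-10, and 0.932 with an estimated correlation). Copies of H4 genes are near-identical, so these are uncertain as separate genes. The interferon-inducible Gbp family also passed upward (adjusted p = 0.00596, and 0.932 with an estimated correlation), with 2 of 10 members called; Gbp4 rose by 0.14 but not without control replicate 2 (0.0538). Of 25 genes of the Cox name root, most of them subunits of cytochrome c oxidase, 3 rose (adjusted p = 0.00692, and 0.932 with an estimated correlation), including Cox7a1 (0.56) and Cox5a (0.38). Cox5a was lost without control replicate 2 or any knockdown array (adjusted p up to 0.072), and of the family 1 passed with median scaling and 0 in the authors' values. In the other direction 3 families passed, each at 0.932 with an estimated correlation: Ints, of Integrator subunits (2 of 15 fell, adjusted p = 0.0184), Cep, of centrosomal proteins (7 of 35 fell, 0.0184), and Kdm, of histone demethylases (4 of 17 fell, 0.0222). With median scaling 1, 5 and 2 of them fell. The adjusted p of 0.932 in camera with an estimated correlation was shared by many of the 312 families, so it does not rank them.

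The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1677 genes and the highest of the others 0, so 1 split gave as many. For 1.5-fold changes it gave 178 and the highest other 9, again 1 split. For gene lists it gave 8 and the highest other 11, so 3 splits gave as many. The other splits that part all 3 numbered pairs gave 7, 3 and 1 lists, and the split that follows the gain groups gave 5 lists and 0 genes. Lists thus also passed in splits that do not follow the groups. Each of the other splits puts arrays of both groups on both sides. The group difference then adds to the spread within each side, so low gene counts there were largely fixed in advance. The groups are also mixed unevenly, so part of their difference stays between the sides. Neither the gene counts nor the lists of these splits are thus a measure of chance.

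Ap4e1 rose by 1.68 on 1 probe. The other probe read 0.06, with a 95% interval that ended at 0.226. This probe had a mean log2 intensity of 6.65, where the offset shrinks differences. Its bound was set after its value was seen. It thus shows no like rise at its own target, but cannot decide whether each transcript rose. A mark on the array surface was argued against by the 8 surrounding spots, whose median difference was 0.0946 (-0.037 to 0.509) against 1.67 for the probe itself. A change in 1 transcript form, or binding of another transcript to that probe, may remain, and neither was tested.

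The changes of the precursor markers were uneven. Of 7 other abundant markers 5 had 95% intervals wholly above that of Pdgfra (-1.581 to -1.138). Rlbp1 (-1.371 to -0.8473) and Lhfpl3 (-1.187 to -0.7271) overlapped it. Pdgfra fell most and was chosen as the reference after the values were seen, so others were likely to lie above it. This comparison cannot decide whether a lower share of precursor cells was the whole cause. Progression to differentiating oligodendrocytes stays open: in that list those that rose less those that fell came to -3, but with the replicate block 4 rose and 4 fell. A change within precursor cells may remain as a hypothesis, and a shift in cell share is not excluded.

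Interferon response genes had a median of 0.0830. A shift of dim probes was argued against, since 10000 of 10000 random lists matched on intensity had a lower median (typically 0.000786). Without both arrays numbered 1 the median was 0.0835. Each group held 1 of them, so a shift equal on both cancels between the groups, and this test could not decide about it. Both groups were infected with a retrovirus, so infection as such was shared. A response to the insert of the knockdown retrovirus, or to unequal infection, may remain. The labels do not tell either apart from the fall of Chd7.

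Pdgfra and Lnx1 lie close together, with Chic2 (-0.38) and Gsx2 (-0.27) between them, both lower in the knockdown; Chic2 was lost without control replicate 3 or knockdown replicates 2 or 3 (adjusted p up to 0.0699). Adjacent genes that passed in the same direction made 97 pairs, against a mean of 80.67 in 10000 random gene orders (95% 64 to 98, one-sided permutation p = 0.0358). Without histone genes there were 91 pairs against 79.09 (permutation p = 0.0909), and without both histone genes and pairs sharing a name root 83 against 70.61 (permutation p = 0.0766). Whether neighbours change together was not settled.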
